A study of Drosophila melanogaster with 8 samples.

How the data were processed

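Whole adult males of the Oregon R and In(1)BM2(reinverted) strains were kept at 24 ± 1 °C or exposed to 12 ± 1 °C for 4 h, with 15 males per sample and 2 samples in each of 4 groups. Per the labels, RNA was extracted with TRIzol and RNeasy, labelled with Cy3 by the Quick-Amp method, and hybridised to 1 array per sample.

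The deposited scanner files were written by Agilent Feature Extraction 10.5.1.1 and hold, per the file headers, the intensity of each spot: a processed signal, background-subtracted and detrended within the array but not normalised between arrays, beside the mean spot signal and median local background. They also hold, per the file headers, other columns of 0 or 1 that mark spots well above background, saturated or non-uniform. The authors' series matrix holds log2 values; set against the scanner files it proved to be the log2 processed signal minus the array's 75th percentile, centred for each probe on the room-temperature mean of its strain (r from 0.990 to 0.997, slopes from 1.00 to 1.01). That centring removes any difference between strains, so the matrix served only as an alternative for the cold comparisons.

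Each array had 45019 spots, 43602 of them non-control, for 32162 distinct probes. The log2 processed signal minus the array's 75th percentile (signals from 2709.6 to 3392) was averaged over duplicate spots. Current gene names were taken from a reference table by locus tag (19190 probes), synonym (546) or accession (164); 126 probes kept the file's name and 12136 had no gene. Positions are those of the files (dm3, BDGP release 5). A gene was represented by its brightest probe over all arrays, and 12386 of 12934 genes had a probe well above background on both arrays of at least 1 group. Of the genes tested, 383 were saturated on at least 1 array. Where no array of a group was well above background, the fold is a lower bound against the background floor of those arrays.

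R 4.3.3, limma 3.58.1 and data.table (version 1.17.8) were used for the analysis, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the plots. One limma fit with 4 group means gave the cold effect in each strain, their difference and the strain difference at each temperature; a fit with strain as a term gave the average cold effect. Spread was shared over groups (4 residual and 2.94 prior degrees of freedom). Calls had a Benjamini-Hochberg adjusted p under 0.05. Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

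Named genes had an adjusted p under 0.05 and arrays of the compared groups that did not overlap, and were the 10 with the largest rise and the 10 with the largest fall (5 and 5 for the average and the strain differences). Added were up to 4 members of each list by moderated statistic, and always the MSL complex, Bar, Fst and Hsp70 genes. Of 28 lists, 27 had at least 3 measured members and were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over lists within a comparison. The median of X-linked minus that of autosomal genes was computed per array, with 95% intervals over arrays, camera and an exact permutation test.

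Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter, a filter for signal on all 8 arrays, the mean of all probes of a gene, an intensity trend in eBayes, a fit of only the groups compared, a replicate block, the series matrix values, leaving out each array in turn, no strain term, other set tests, and for the X chromosome the mean and genes outside the testis and accessory gland lists. Leaving out probes saturated on any array, normexp with the local background of defective spots set to the array's median background, and a crossed pairing were added after seeing the data. Tested on simulated data of the same size, the fit recovered 70% of genes changed by 0.5 and 98% of those changed by 1 (log2) in reinverted males, and 30% and 98% for the difference between strains, with 6 and 8 false calls among 12101 unchanged genes. The simulated noise was independent between genes and between arrays. The real arrays can depart from that, so these rates need not hold for them.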

Results

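Gene expression was measured in whole adult Drosophila melanogaster males of 2 strains, each kept at room temperature (24 ± 1 °C) or given a cold shock (12 ± 1 °C for 4 h). Oregon R is a wild-type laboratory strain. In(1)BM2(reinverted), here called the reinverted strain, carries an X chromosome that was inverted in the Bar region and later returned to the standard order, and it is known for a male X chromosome whose morphology depends on temperature. Each of the 4 groups had 2 samples of 15 males, which the series describes as biological replicates, and each sample was hybridised to 1 Cy3-labelled Agilent array, 8 arrays in all. On the Oregon R arrays 82.7% to 83.8% of probes were well above background, and on the reinverted arrays 78.0% to 80.9%. Between 418 and 462 probes per array were saturated. Replicate arrays of a group correlated at 0.995 to 0.998 (Pearson r across genes). The number of arrays, 2 per group, limits the precision of every value. The arrays of a strain shared a slide, so strain and slide cannot be told apart; on both slides the room-temperature arrays also lay in the first 2 positions, so array position and temperature coincide. Levels are log2 signals relative to the 75th percentile of the array, changes are log2 differences with the standard error (SE) of the fit, and adjusted p values come from limma with Benjamini-Hochberg adjustment over 12386 genes.

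The first comparison asked which genes changed in reinverted males after the cold shock, the question in the series title. Frost (Fst), a gene known for its strong induction during recovery from cold, rose from -2.85 ± 0.03 (SD, n = 2) to 2.30 ± 0.13 (SD, n = 2), a log2 change of 5.16 (SE 0.17, adjusted p = 5.8e-05) at its probe on chromosome arm 3R (5470906 to 5470965, dm3). CG13454 was not well above background on either room-temperature array and was at least 53.1-fold higher after cold (3L, 15509658 to 15509717, adjusted p = 2.2e-04). The antimicrobial peptide gene CecC was at least 8.91-fold higher, CG34217 at least 7.44-fold, CG10183 at least 4.13-fold, Osi23 at least 2.79-fold and CG14089 at least 2.10-fold, each against room-temperature arrays without signal well above background. Among genes measured on both sides, CG10182 rose by 4.16, CG13325 by 3.19 and CG13482 by 3.16. CecC no longer passed without room-temperature replicate 1 or without cold-shock replicate 1.

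The deepest falls in reinverted males were smaller than the largest rises. The gustatory receptor gene Gr98a fell by 2.39 (SE 0.16, adjusted p = 3.0e-04), the glycosyltransferase gene Ugt303A1 fell by 2.21, CG11741 by 1.99, lectin-28C by 1.78 and the serine protease gene Ser8 by 1.77. The pair-rule transcription factor gene odd had a log2 change of -1.67, Elo68beta of -1.61, and CG8089, CG3348 and CG30431 each of -1.55. In all, 1988 genes passed the threshold, 1002 higher and 986 lower after cold, of which 158 rose and 42 fell by more than 2-fold. Leaving out 1 array changed this count to 966 (without room-temperature replicate 1), 817 (without cold-shock replicate 1) or 827 (without cold-shock replicate 2).

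Several gene lists fixed before the data were examined shifted in reinverted males, by limma's camera test with a preset correlation between genes. Of 28 measured antimicrobial peptide and immune genes, 27 had a positive change, 7 rose (9 when adjusted over the list alone) and none fell (median 0.74, adjusted p = 1.7e-05, or adjusted p = 0.87 with an estimated correlation). Rel, the NF-kappaB factor of the Imd pathway, rose by 1.02 (SE 0.07), the cecropin gene CecA1 by 1.64 and the peptidoglycan recognition gene PGRP-SC2 by 0.41. Of 9 genes earlier reported to respond to cold, 5 rose and none fell (5 and 1 when adjusted over the list alone; median 0.50, adjusted p = 5.7e-04, or adjusted p = 0.38 with an estimated correlation), among them the Hsp70 cochaperone gene stv by 0.78, CG10912 by 0.91 and the desaturase gene Desat2 by 1.03. Of 68 glutathione and UDP-glycosyl transferase genes, 18 rose and 5 fell (23 and 6 over the list alone; adjusted p = 4.0e-04, or adjusted p = 0.87 with an estimated correlation); GstE3 rose by 1.84 and Ugt302C1 by 0.80. Of 86 cuticle protein genes, 11 rose and 2 fell (11 and 2 over the list alone; adjusted p = 0.0065, or adjusted p = 0.87 with an estimated correlation), with Cpr67Fb at 1.52 and Cpr72Ec at 1.07. The immune list did not pass when fry, which asks whether a set moves on balance in 1 direction, replaced camera, and the cuticle list did not pass without cold-shock replicate 1. The estimated correlation was 0.41 for the immune list, 0.13 for the transferases, 0.040 for cuticle proteins and -0.029 for the genes reported to respond to cold. The last lies under the preset 0.01, yet the unadjusted camera p of that list rose from 6.3e-05 to 0.014. Correlation between its genes thus does not account for its lost call.

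Heat shock proteins and chaperones went the other way in this strain: 7 of 26 fell and 2 rose (9 and 2 over the list alone; median -0.11, adjusted p = 0.034, or adjusted p = 0.87 with an estimated correlation). The list was no longer called without room-temperature replicate 1, room-temperature replicate 2 or cold-shock replicate 1. Hsp70Aa changed by -1.10 (SE 0.08), Hsp70Bc by -0.89, Hsp70Bbb by -0.85 and the cochaperone gene DnaJ-1 by -1.09, and Hsp70Bb had -0.52 without passing the threshold. The Hsp70 copies are nearly identical in sequence, so signal from 1 copy at the probe of another was not excluded. Oxidative phosphorylation genes (median 0.10, 1 of 32 called) and ribosomal protein genes (median 0.09, 0 of 93 called by limma; 2 at an unadjusted p under 0.05) also passed camera at adjusted p = 0.0083 and 0.0065, with adjusted p = 0.92 for both with an estimated correlation, but 16 and 72 of them were saturated on at least 1 array. Neither list passed after quantile normalization, with fry, without room-temperature replicate 2 or without cold-shock replicate 2, and the ribosomal list was also lost without probes saturated on any array. Socs36E, a target of JAK-STAT signalling, rose by 1.52, while its list did not pass (adjusted p = 0.32).

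Core clock genes changed after cold in reinverted males without the list of 13 passing camera (adjusted p = 0.14), while with fry it passed (adjusted p = 0.039). In reinverted males per rose by 1.36 (SE 0.11), vri by 1.33 and to, a clock output gene, by 1.47, while tim had -1.48 (SE 0.09) at its brightest probe (2L, 3493991 to 3494050, dm3). In all, 5 of the 13 rose and 2 fell (6 and 2 over the list alone). A second tim probe (2L, 3501126 to 3501185, dm3) rose by 5.90 in the same males, so the direction for tim holds for the brightest probe only, and the mean of both probes gave 2.21.

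**Figure D1:**
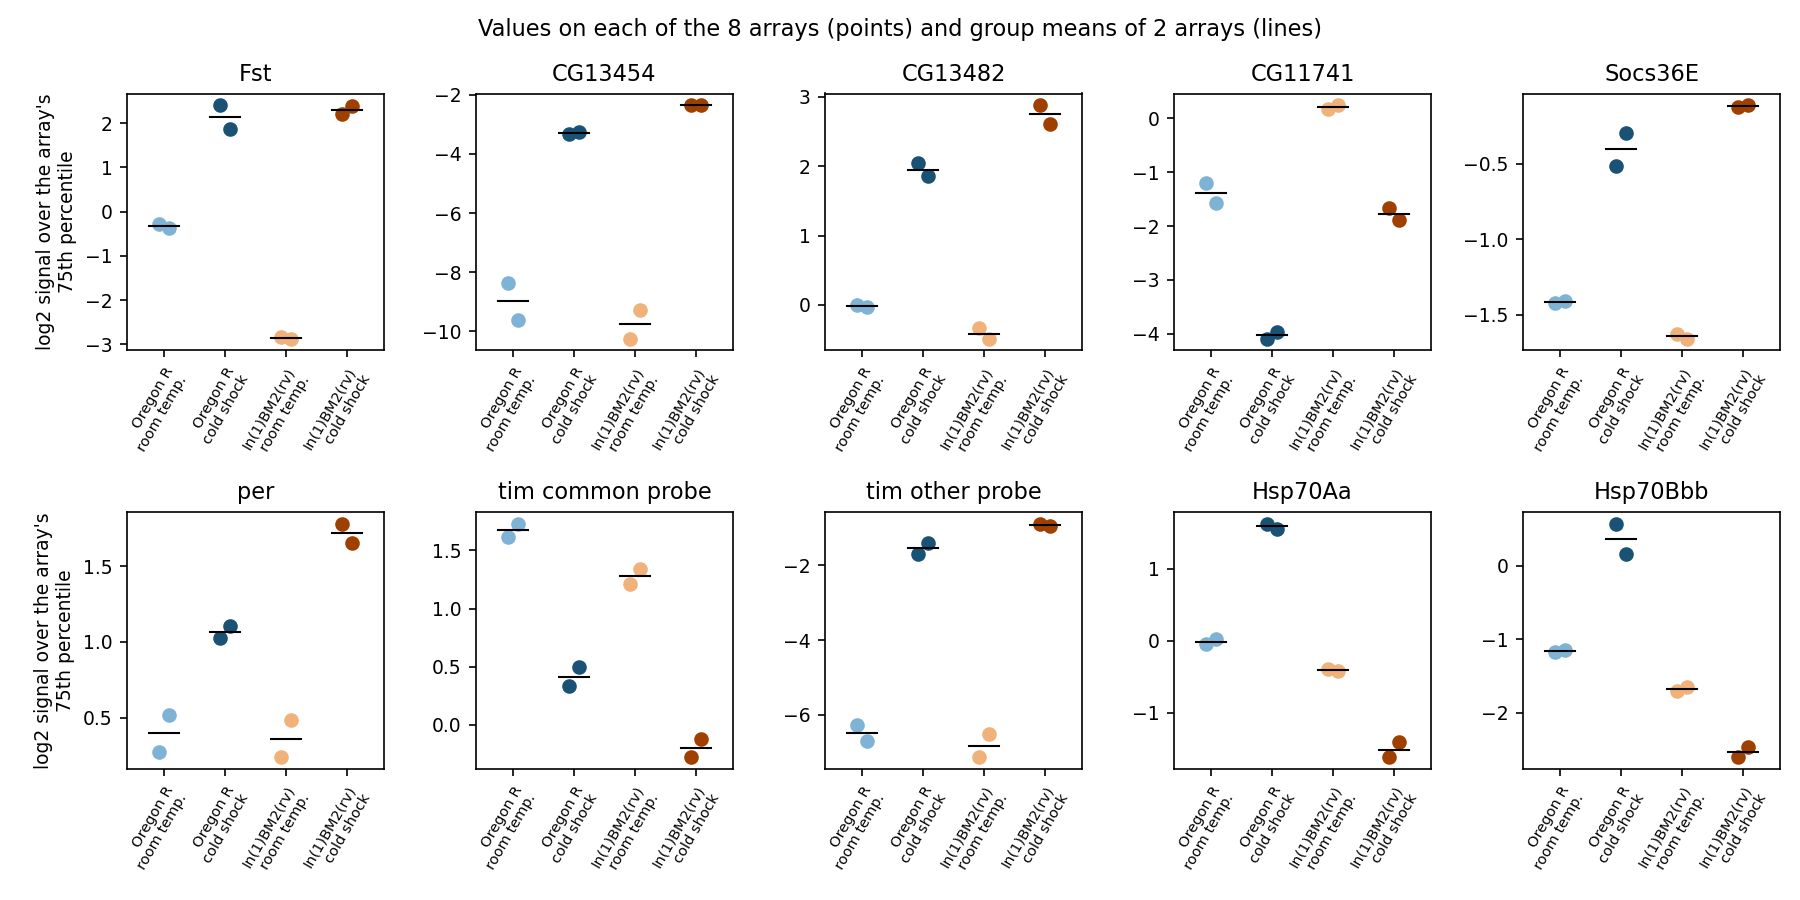
Log2 signal relative to the array's 75th percentile (vertical axes) of 8 genes and of both tim probes on each of the 8 arrays. Points are arrays, coloured by group, and lines are means of 2 arrays. The panel titled tim common probe holds the brightest tim probe. After cold Fst reached 2.13 in Oregon R and 2.30 in reinverted males from unequal starting levels, and Hsp70Aa moved in opposite directions in the 2 strains.

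The same cold shock was compared in Oregon R males. CG13454 was again below background at room temperature and was at least 32.4-fold higher after cold (adjusted p = 8.3e-04). Fst rose from -0.32 ± 0.07 (SD, n = 2) to 2.13 ± 0.39 (SD, n = 2), a log2 change of 2.45 (SE 0.17, adjusted p = 7.4e-04). CG34217 rose by 2.60, CG14219 by 2.56, the cuticle protein gene Cpr67Fb by 2.47 and CG10039 by 2.37, and the non-coding RNA gene CR30121 (lncRNA:CR30121) was at least 3.93-fold higher. CG14089 and SNCF were at least 1.43-fold and 1.54-fold higher. CG32551, at least 1.70-fold higher, held under 10 of 19 alternatives and was lost, among others, without either room-temperature replicate. Among the falls, CG11741 had a log2 change of -2.65 (SE 0.13, adjusted p = 4.3e-04), CG3739 of -2.06, Gr98a of -1.89, CG6793 of -1.61, Dtwd2 of -1.51, CG34406 of -1.50 and zye of -1.43. The gene mey was at least 1.23-fold and the receptor gene Ir56b at least 1.54-fold lower; E(spl)m6-BFM passed the threshold but was not well above background in either group.

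In Oregon R males 3854 genes passed, 1803 higher and 2051 lower, of which 91 rose and 47 fell by more than 2-fold. With each array centred on its median the balance turned, to 2133 higher and 1624 lower. The count was 2525 without room-temperature replicate 1, 1144 without room-temperature replicate 2, 1806 without cold-shock replicate 1, and 2147 when only the 4 Oregon R arrays were fitted. Cold-shock replicate 1 carried eggshell and yolk transcripts: the median of 15 female markers lay 3.28 above the room-temperature mean on that array and 0.11 above it on replicate 2. Room-temperature replicate 2 had high yolk protein signals as well, with Yp1 at 0.87, Yp2 at 0.81 and Yp3 at 1.14. On room-temperature replicate 1 these lay at -3.54, -3.47 and -0.72. The eggshell gene Cp36 was low on room-temperature replicate 2 (-6.67).

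Hsp70 genes rose in Oregon R males, Hsp70Aa by 1.60 (SE 0.08, adjusted p = 4.3e-04), Hsp70Bb by 1.71, Hsp70Bbb by 1.52 and Hsp70Bc by 1.19. The whole list of heat shock proteins and chaperones, with 6 higher and 5 lower of 26 (7 and 6 over the list alone), did not pass camera (adjusted p = 0.33) but passed fry (adjusted p = 0.042). Rel rose by 1.01 (SE 0.07), pirk, a negative regulator of the Imd pathway, by 2.22, Socs36E by 1.01 and stv by 0.50. Of 28 immune genes 3 rose and none fell (3 over the list alone; camera, adjusted p = 0.069). The clock genes per and cwo rose by 0.67 and 0.59, and tim had -1.26 (SE 0.09) at its brightest probe, with its second probe at 4.93 and the mean of both at 1.84. Of the 13 clock genes 4 rose and 2 fell (4 and 3 over the list alone). The clock list passed neither camera (adjusted p = 0.94) nor fry (adjusted p = 0.59). The call of cwo was lost without room-temperature replicate 2.

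In Oregon R males 11 of 34 testis markers rose, none fell and 23 did not pass (11 over the list alone; median 0.18, adjusted p = 0.0013, or adjusted p = 0.88 with an estimated correlation). The sperm chromatin protein genes ProtB and ProtA rose by 0.43 (SE 0.07) and 0.34, the sperm leucylaminopeptidase gene S-Lap5 by 0.40 and djl by 0.30. Without room-temperature replicate 2 ProtA, S-Lap5 and djl no longer passed, and djl was also lost without cold-shock replicate 1. Of 9 measured Y-linked genes, which serve male fertility, 7 rose and none fell (7 over the list alone; median 0.36, adjusted p = 0.012, or adjusted p = 0.93 with an estimated correlation), among them kl-2 by 0.45, Ppr-Y by 0.42, Pp1-Y2 by 0.41 and kl-5 by 0.35. None of these 4 calls held without room-temperature replicate 2, and Ppr-Y, Pp1-Y2 and kl-5 were also lost without cold-shock replicate 1. Of 45 proteasome genes 10 rose (10 over the list alone), and the list passed fry (adjusted p = 0.018) but not camera (adjusted p = 0.069). Prosbeta5R1 at 0.41, Prosalpha6T at 0.36 and Prosbeta2R1 at 0.31 are variants of proteasome subunits known from the male germ line; these 3 calls were lost without room-temperature replicate 2, and the last 2 also without cold-shock replicate 1. The Y-linked list did not pass with fry, and its median was -0.20 with normexp background correction, which failed on Oregon R room-temperature replicate 2. Without cold-shock replicate 1, the array with eggshell transcripts, the testis median was 0.16.

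**Figure D2:**
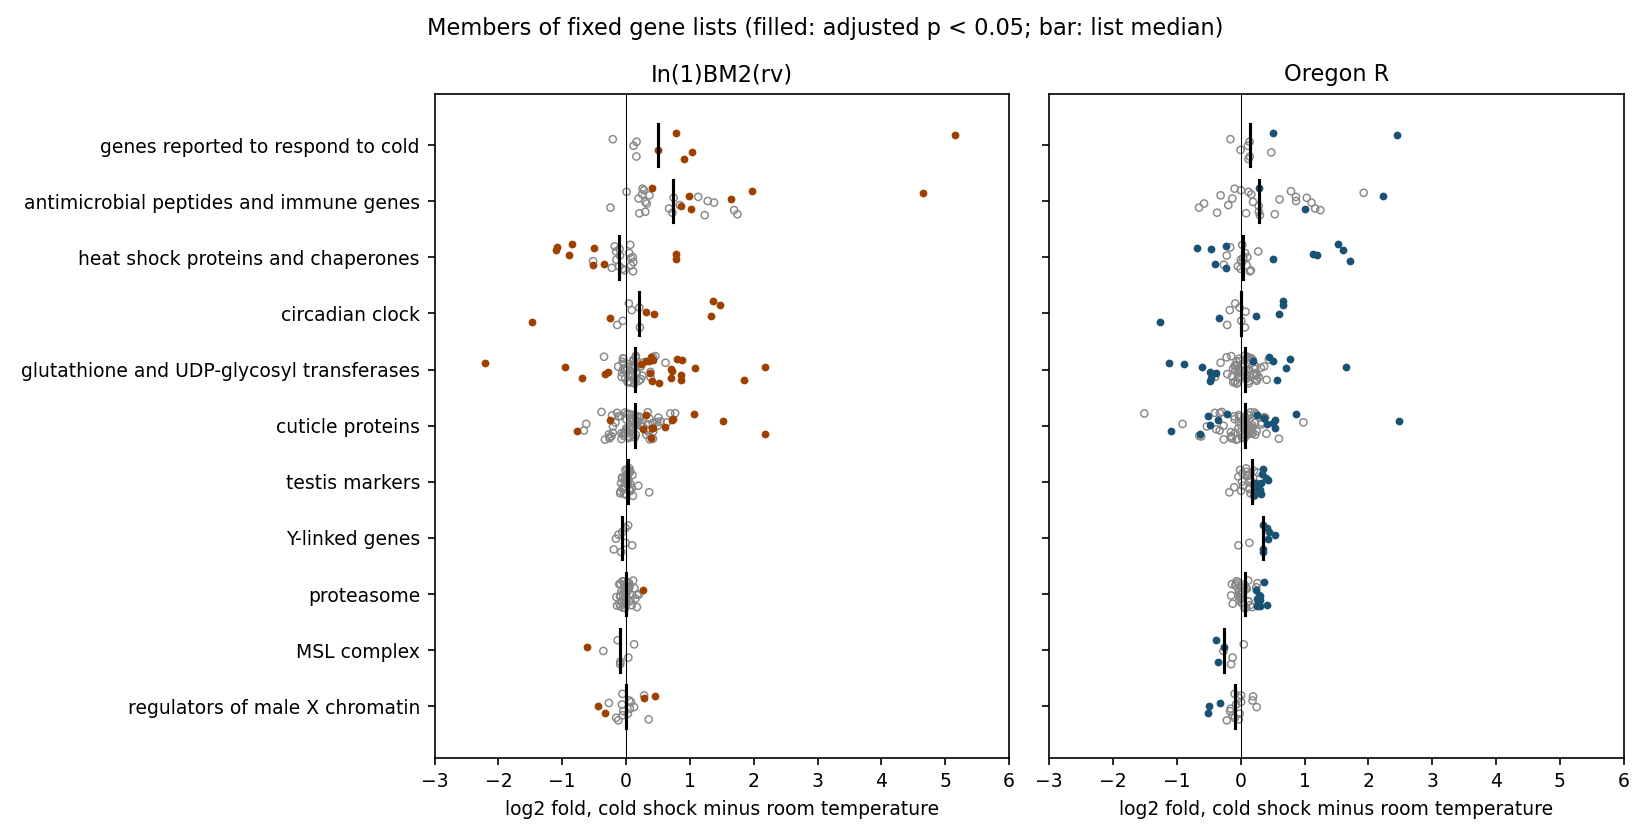
Log2 change after cold (horizontal axes) of every measured member of 11 fixed gene lists in reinverted In(1)BM2 males (left) and Oregon R males (right); filled points passed an adjusted p of 0.05, open points did not, and bars are list medians. The immune list has its median at 0.74 in the reinverted strain and 0.28 in Oregon R (-0.03 on cold-shock replicate 1 and 0.48 on replicate 2), and the Y-linked list at -0.06 and 0.36; the difference between strains did not pass camera for the immune list (adjusted p = 0.13).

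The cold responses of the 2 strains, which share no array, were then set side by side. Genes higher after cold in both strains numbered 471, against 145.86 expected of independent lists, and 778 were lower in both, against 163.27. Fewer were higher without Oregon R room-temperature replicate 1 (309) or 2 (248) or reinverted cold-shock replicate 1 (263) or 2 (285). Fewer were lower without Oregon R room-temperature replicate 2 (429), reinverted room-temperature replicate 1 (338) or 2 (485), or reinverted cold-shock replicate 1 (295) or 2 (263). Opposite calls were made for 19 genes, against 309.45. Both cold effects used 1 fitted spread per gene, so genes of low spread tend to be called in both strains, whatever the direction. The expected counts do not allow for that. Across all 12386 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.55 and Spearman rho = 0.51. Array position followed temperature in both strains, so for these counts position and cold cannot be told apart. The 19 opposite genes included Hsp70Aa, Hsp70Bbb, Hsp70Bc, the gustatory receptor gene Gr89a and the cytochrome P450 gene Cyp6a2, which rose by 0.71 in reinverted males and had -1.06 in Oregon R. In reinverted males the call of Cyp6a2 was lost without cold-shock replicate 1 (adjusted p = 0.076) or 2 (adjusted p = 0.0501) and with normexp (adjusted p = 0.096).

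Averaged over both strains, with strain as a term, 3024 genes passed, 1113 higher and 1911 lower. Fst rose by 3.80 (SE 0.49, adjusted p = 0.0015), and CG13454, CecC, CG34217 and CG14089, each at or below background on some room-temperature arrays, completed the 5 largest rises. CG11741 fell by 2.32, Gr98a by 2.14, CG3739 by 1.76, Ugt303A1 by 1.67 and CG6793 by 1.56. Rel rose by 1.01 (SE 0.05), Socs36E by 1.27, the lipid droplet gene Lsd-2 by 0.86, stv by 0.64, cwo by 0.52 and GstE7 by 1.91, while Hsp60A fell by 0.38 and the chromatin gene pzg by 0.47. Of the lists, immune genes (9 of 28 rose, 9 over the list alone; adjusted p = 7.2e-04), genes reported to respond to cold (4 rose and 1 fell of 9, 6 and 1 over the list alone; adjusted p = 0.017), and glutathione and UDP-glycosyl transferases (18 rose and 5 fell of 68, 22 and 6 over the list alone; adjusted p = 0.016) passed, with adjusted p = 0.91 for each with an estimated correlation. Oxidative phosphorylation, testis, female, ribosomal and cuticle lists also passed by camera as higher, at adjusted p from 0.0043 to 0.038, and each had adjusted p = 0.91 with an estimated correlation. Called by limma were 1 of 32 oxidative phosphorylation genes (0 over the list alone), 0 of 34 testis, 0 of 15 female and 0 of 93 ribosomal genes. Of 86 cuticle genes 12 rose and 5 fell (11 and 5 over the list alone). With fry only the genes reported to respond to cold still passed of these 8 lists, and without probes saturated on any array the oxidative phosphorylation and ribosomal lists were lost. Without reinverted room-temperature replicate 2 only the immune and testis lists of these 8 still passed. Without Oregon R room-temperature replicate 1 the oxidative phosphorylation, testis, female, ribosomal and cuticle lists were lost, and without Oregon R cold-shock replicate 1 the testis, female and cuticle lists. Oxidative phosphorylation was also lost without cold-shock replicate 2 of either strain, and cuticle proteins without replicate 1 of either reinverted group. Without the strain term 775 genes passed.

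**Figure D3:**
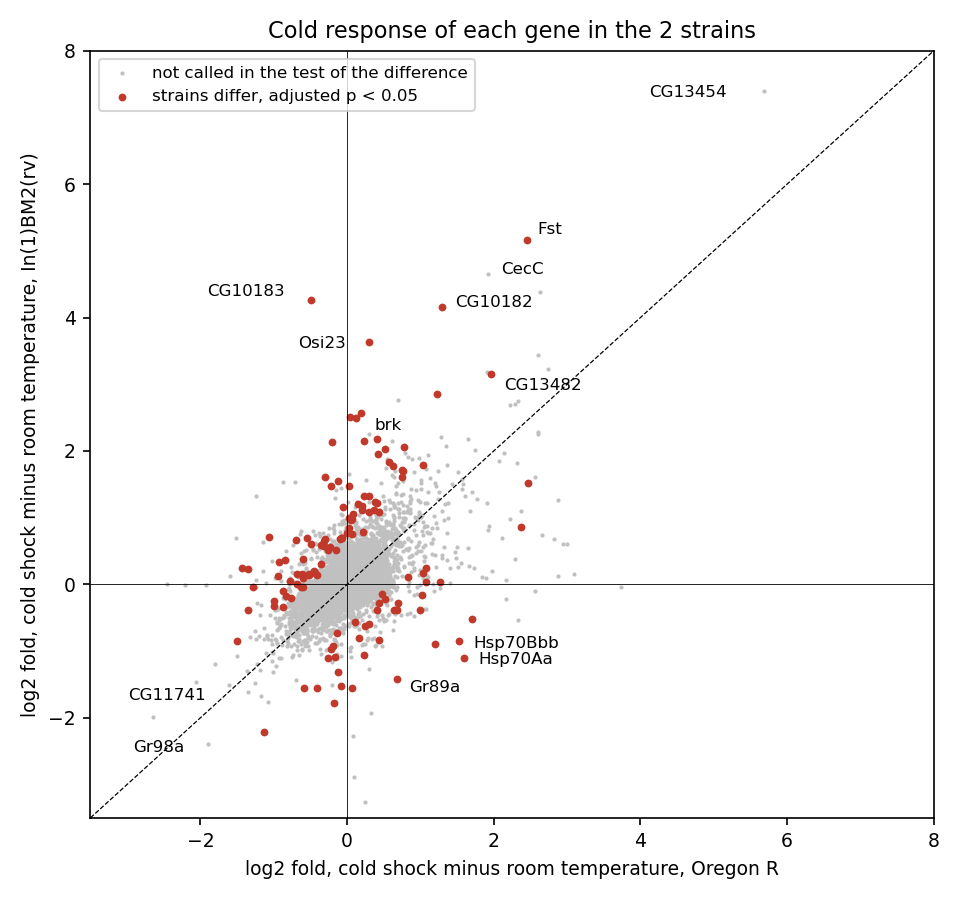
Log2 change after cold of 12386 genes in Oregon R (horizontal axis) and in reinverted In(1)BM2 males (vertical axis), 1 point per gene; red points are the 125 genes whose cold effects differed between strains, and the dashed line marks equal change. Fst, CG10182 and CG13482 lie above the line, and Hsp70Aa and Hsp70Bbb fall where Oregon R rose and the reinverted strain fell.

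Whether the strains responded differently was tested directly, as the reinverted minus the Oregon R cold effect. Fst differed by 2.70 (SE 0.23, adjusted p = 0.0079): its level after cold was similar in both strains (2.30 and 2.13), while at room temperature it lay at -2.85 in the reinverted strain and -0.32 in Oregon R. The genes with the largest positive differences also included CG10182 (2.86), CG11854 (2.48), CG33346 (2.33), brk, a transcriptional repressor of Dpp targets (1.92), and CG14342 (1.91). For CG10183 (4.75), Osi23 (3.34), CG11470 (2.38) and CG7606 (2.37) the fitted difference rests in part on groups not well above background and is not a measured fold. The Hsp70 genes had negative differences, with Hsp70Aa at -2.70 (SE 0.12, adjusted p = 0.0011), Hsp70Bbb at -2.37, Hsp70Bb at -2.22 and Hsp70Bc at -2.09. Negative differences were also found for CG3348 (-1.62), lectin-28C (-1.60), CG10039 (-1.50), CG7025 (-1.44) and Burs, which encodes a subunit of the hormone bursicon (-1.38). Gr89a passed as well, but its fitted -2.09 rests on a group not well above background, the reinverted strain after cold, and is not a measured fold. Many of these calls were lost when 1 array was left out. Of the alternatives run, CG10039 held under 8 of 19, lectin-28C and CG7025 under 12, CG10182 under 13, Burs and CG14342 under 14 and CG3348 under 15. The arrays whose absence lost a call were reinverted cold-shock replicates 1 and 2 for CG10039, lectin-28C, CG7025, CG10182 and CG3348, and Oregon R cold-shock replicate 1 for CG10039, lectin-28C, CG7025, CG10182, Burs, CG14342 and CG10183. Further losses came without Oregon R room-temperature replicate 1 (lectin-28C, CG7025, Burs, CG14342) or 2 (these 4, CG10039 and CG7606), Oregon R cold-shock replicate 2 (CG10039), reinverted room-temperature replicate 1 (CG10039, CG10182, CG3348, Burs) or 2 (CG10039, CG10182), or reinverted cold-shock replicate 1 (CG14342, CG10183).

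In the same test GstE3 (1.26), Cyp6a2 (1.77), the lysozyme gene LysS (1.25) and vri (1.09) had positive differences, and Cpr67Fb (-0.95) and Ugt303A1 (-1.08) negative ones. Of these, LysS held under 9 of 19 alternatives and Cpr67Fb and Ugt303A1 under 11. All 3 were lost with a replicate block and without Oregon R room-temperature or cold-shock replicate 1, reinverted room-temperature replicate 1 or either reinverted cold-shock replicate. LysS was also lost without reinverted room-temperature replicate 2, and Cpr67Fb and Ugt303A1 without Oregon R room-temperature replicate 2. GstE3 and Cyp6a2 were lost without reinverted cold-shock replicate 1, and Cyp6a2 without Oregon R room-temperature replicate 2. Of the fixed lists, testis markers (median -0.17, 28 of 34 negative) and Y-linked genes (median -0.42, 8 of 9 negative) passed at adjusted p = 4.9e-04 each, although 0 of their members passed by limma over all genes (0 testis and 7 Y-linked genes when adjusted over the list alone; 10 and 7 at an unadjusted p under 0.05). Heat shock proteins (5 lower, 0 higher of 26, or 6 and 1 over the list alone; adjusted p = 0.010), genes reported to respond to cold (1 higher of 9, or 2 over the list alone; adjusted p = 0.036) and proteasome genes (median -0.03, 0 called by limma, 7 at an unadjusted p under 0.05; adjusted p = 0.036) also passed. Each of these 5 lists had adjusted p = 0.69 with an estimated correlation. With fry the testis and Y-linked lists (adjusted p = 0.11 for each) and the proteasome list (adjusted p = 0.089) did not pass. The heat shock list no longer passed without Oregon R cold-shock replicate 2. Its 5 lower genes included Hsp70Aa, Hsp70Bbb, Hsp70Bb and Hsp70Bc, whose probes may share signal. Of its 26 genes 11 had a positive difference (median -0.027), so the call does not describe the list as a whole. The cold-reported list was lost without Oregon R room-temperature replicate 2 or cold-shock replicate 1, or reinverted room-temperature replicate 2 or cold-shock replicate 2, and the proteasome list without Oregon R cold-shock replicate 1, reinverted room-temperature replicate 1 or cold-shock replicate 2. In all 125 genes differed, 86 with a higher and 39 with a lower cold effect in the reinverted strain, and this count was the least stable of the comparisons: it was 52 (40 higher, 12 lower) and 33 (22 and 11) without Oregon R room-temperature replicates 1 and 2, and 46 (30 and 16) and 278 (138 and 140) without Oregon R cold-shock replicates 1 and 2. It was 51 (32 and 19) without reinverted room-temperature replicate 1, and 31 (17 and 14) and 47 (36 and 11) without reinverted cold-shock replicates 1 and 2. The excess of higher effects was thus absent without Oregon R cold-shock replicate 2.

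Because the reinverted strain is known for its male X chromosome, X-linked genes were compared with autosomal ones. The median of 1971 X-linked genes lay below that of 10310 autosomal genes by a similar amount on every array, with differences from -0.39 to -0.35. Cold changed this difference by 0.001 in reinverted males (95% interval -0.036 to 0.038) and by 0.003 in Oregon R (-0.034 to 0.041), and the change differed between strains by -0.002 (-0.055 to 0.050). Camera gave p = 0.77, 0.84 and 0.85 for these 3 tests, and the exact 2-sided permutation test gave p = 1 in both strains, where 2 arrays against 2 cannot give less than 0.33. Between strains the difference was -0.016 at room temperature (-0.053 to 0.022) and -0.018 after cold (-0.055 to 0.019). Over both strains the cold changed it by 0.002 (-0.024 to 0.029).

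Of the 7 MSL complex genes, which encode the male dosage compensation machinery, roX2 (lncRNA:roX2) fell by 0.61 in reinverted males (SE 0.08, adjusted p = 0.0034) and by 0.26 in Oregon R. In Oregon R mof had -0.39 and msl-2 had -0.35, both past the threshold. In reinverted males mof had -0.13, msl-2 -0.09, msl-1 -0.36 and roX1 (lncRNA:roX1) -0.09, none of which passed. By camera the MSL list did not pass in reinverted or Oregon R males (adjusted p = 0.24 and 0.12), while fry called it lower in both (adjusted p = 0.044 and 0.018) and on average (adjusted p = 0.020, 3 of 7 lower). The difference between strains did not pass for roX2 (-0.34), mof (0.26) or msl-2 (0.26). In Oregon R the call of mof was lost without room-temperature replicate 1, room-temperature replicate 2 or cold-shock replicate 1, that of roX2 without any 1 of that strain's 4 arrays, and that of msl-2 held under 7 of 20 alternatives. Among 18 regulators of male X chromatin, 2 rose and 2 fell in reinverted males (4 and 3 over the list alone) and 3 fell in Oregon R (3 over the list alone). By camera the list did not pass in either strain (adjusted p = 0.94 and 0.33). The chromatin gene pzg had -0.44 and -0.50, Trl, which encodes the GAGA factor, -0.33 and -0.51, and Clamp, which encodes an MSL recruitment factor, rose by 0.45 in reinverted males. In reinverted males the call of Trl held under 10 of 20 alternatives, that of Clamp was lost without room-temperature replicate 2 or cold-shock replicate 2, and that of pzg without cold-shock replicate 2. In Oregon R the call of Trl was lost without room-temperature replicate 2.

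**Figure D4:**
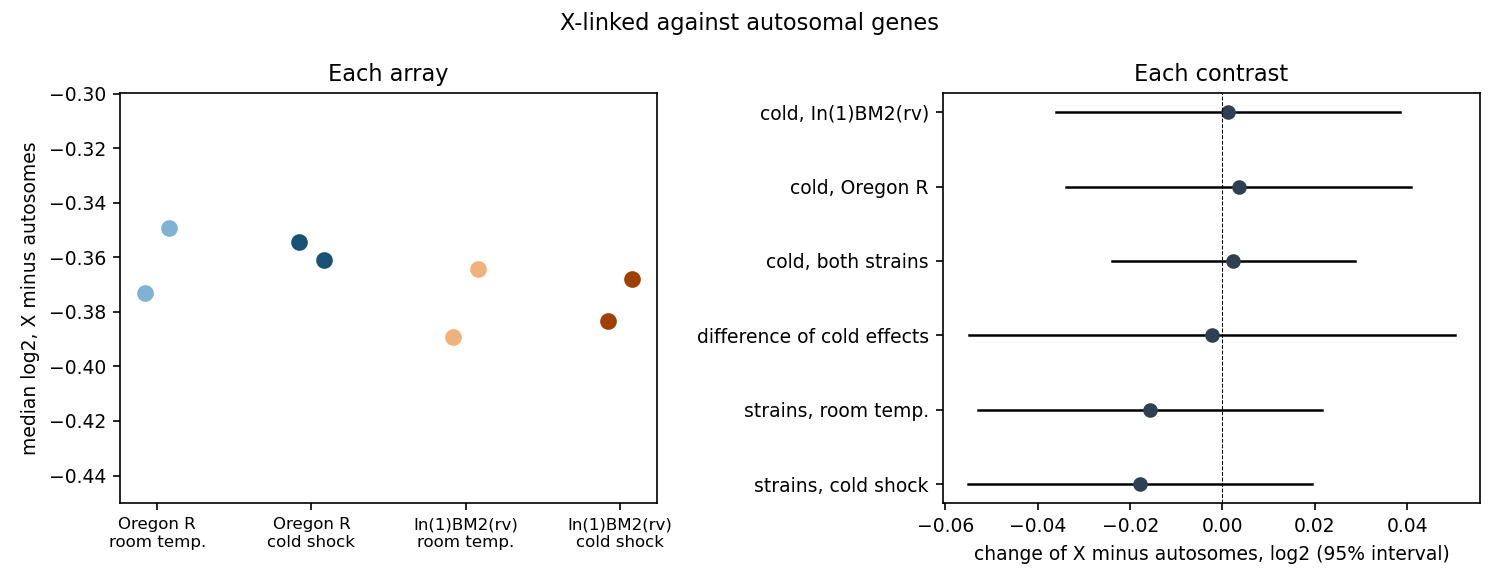
Left, median log2 signal of X-linked minus autosomal genes on each of the 8 arrays (points, by group). Right, change of that difference in each of 6 contrasts (points) with its 95% interval over arrays (lines); every interval includes 0.

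The strains were last compared at the same temperature, reinverted minus Oregon R, where slide and strain coincide and a sequence difference under a probe would also count. At room temperature hemocyte genes were higher in the reinverted strain: 8 of 11 were higher and none lower (8 over the list alone; median 0.95, adjusted p = 0.0048, or adjusted p = 0.83 with an estimated correlation). The clotting factor gene Hml was higher by 4.24 (SE 0.26), the prophenoloxidase genes PPO1 and PPO2 by 3.49 and 2.29 and the phagocytosis receptor gene eater by 1.81. Immune effectors were lower, 15 of 28 against 1 higher (15 and 1 over the list alone; adjusted p = 0.0048, or adjusted p = 0.83 with an estimated correlation), with BomBc1 at -4.74, BomS1 at -4.63 and PGRP-SC2 at -1.46. Of 19 accessory gland genes 10 were lower and none higher (10 over the list alone; adjusted p = 0.0048, or adjusted p = 0.83 with an estimated correlation), with the seminal fluid protein genes Acp29AB at -3.44 and Acp76A at -2.11. Of 46 odorant binding protein genes 27 were lower and 10 higher (29 and 10 over the list alone; adjusted p = 0.019, or adjusted p = 0.83 with an estimated correlation).

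Among single genes at room temperature, CG8531 was at least 2528-fold, Cyp4ac1 at least 1441-fold, Su(P) at least 939-fold, CG31870 at least 736-fold and CG32551 at least 408-fold higher in the reinverted strain, each not well above background on the Oregon R arrays of that temperature. CG8329 was at least 227-fold and CG1575 at least 133-fold lower. The genes ppl, CG31872 and CG1304 were also lower, but each was well above background on 1 of the 2 reinverted arrays, so their fitted differences of -10.14, -10.03 and -9.01 are not measured folds. These moved to -7.07, -7.28 and -6.51 without reinverted room-temperature replicate 2, and to -13.20, -12.78 and -11.50 without replicate 1. The Y-linked gene Pp1-Y1 was at least 41.8-fold higher. The tryptophan oxygenase gene v was higher by 3.26, the takeout gene to by 2.48 and Cyp9b1 by 4.66, while the storage protein gene Lsp2 was lower at -3.88, fit at -3.69 and the stress-response gene TotX at -4.85. The Bar homeobox genes B-H1 and B-H2, which flank the Bar region, had -0.52 and -0.32, both past the threshold, but the call of B-H1 was lost without Oregon R room-temperature replicate 2 and that of B-H2 without any 1 of the 4 room-temperature arrays. In all 5661 genes passed, 2488 higher and 3173 lower; with each array centred on its median 57.6% of the calls were higher and with quantile normalization 53.0%, against 43.95%.

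After cold the strains differed at 6082 genes, 2941 higher and 3141 lower in the reinverted strain. The balance turned with quantile normalization (3283 higher and 2762 lower) and with each array centred on its median (3332 and 2692). The same 4 lists passed: hemocyte genes higher (8 of 11, and 8 over the list alone; adjusted p = 0.0038), and immune (13 of 28 lower, and 13 over the list alone; adjusted p = 0.024), accessory gland (11 of 19 lower, and 12 over the list alone; adjusted p = 0.0038) and odorant binding protein genes (26 of 46 lower, and 26 over the list alone; adjusted p = 0.042), with adjusted p = 0.98 for each with an estimated correlation. Fst no longer differed past the threshold (0.17, SE 0.17). The Hsp70 genes were lower in the reinverted strain, Hsp70Aa at -3.09 (SE 0.08), Hsp70Bbb at -2.90, Hsp70Bb at -2.75 and Hsp70Bc at -2.46. CG30429, CG31870, CG31955 and Fam92 were at least 758-fold, 736-fold, 201-fold and 193-fold higher, and CG17633, CG31872, ppl, CG12289 and CG1304 at least 6622-fold, 4389-fold, 2151-fold, 639-fold and 614-fold lower. B-H1 had -0.44 and roX2 (lncRNA:roX2) -0.46, both past the threshold, and B-H2 -0.10, which did not pass. The call of B-H1 was lost without Oregon R or reinverted cold-shock replicate 2, and the immune and odorant binding protein lists without Oregon R cold-shock replicate 2. The odorant binding protein list was also lost after quantile normalization, with the mean of all probes and without probes saturated on any array.

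**Figure D5:**
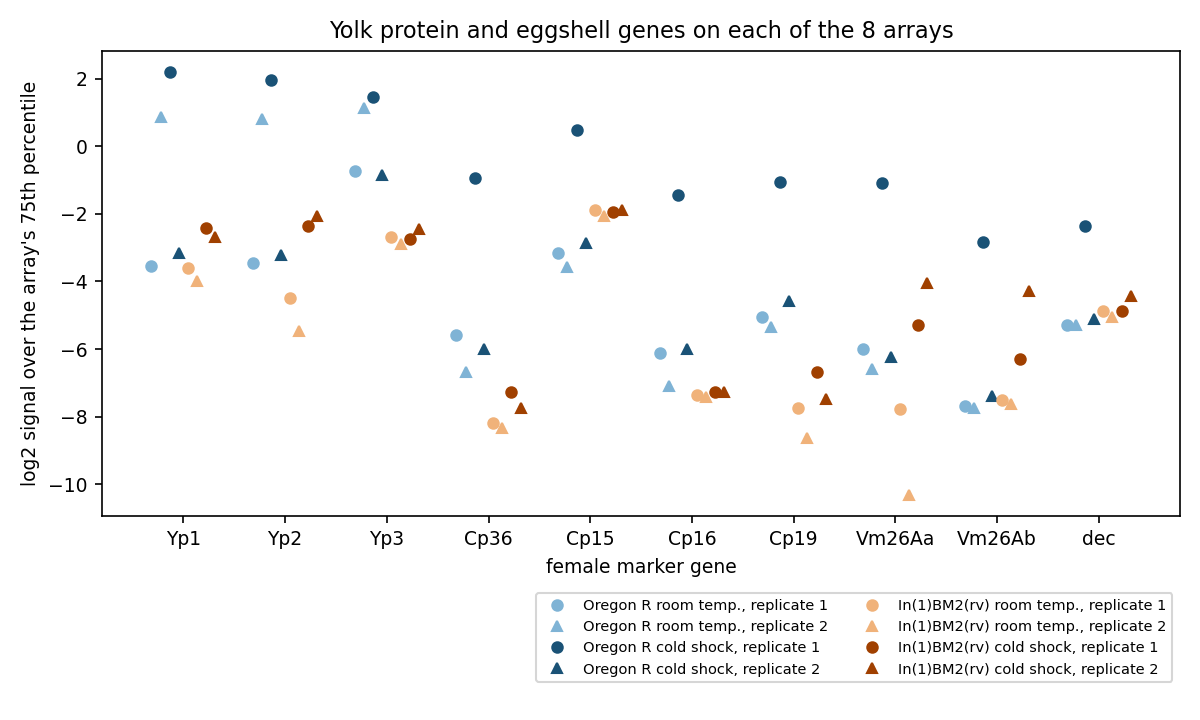
Log2 signal relative to the array's 75th percentile (vertical axis) of 10 yolk protein and eggshell genes (horizontal axis) on the 8 arrays, coloured by group, with circles for replicate 1 and triangles for replicate 2. Eggshell genes such as Cp36 (-0.93 against -6.01 on replicate 2) stand out on Oregon R cold-shock replicate 1, and Yp1 and Yp2 were also high on Oregon R room-temperature replicate 2.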

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

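The tests of the cold shock itself as the source of female transcripts, and both tests on tim and per, were chosen only after the result was seen.

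The cold effect differed between strains by the test of the difference itself at 10 named genes with a higher and 10 with a lower effect in reinverted males. The positive differences were 2.86 for CG10182, 2.70 for Fst, 2.48 for CG11854, 2.33 for CG33346, 1.92 for brk and 1.91 for CG14342. The negative differences were -2.70 for Hsp70Aa, -2.37 for Hsp70Bbb, -2.22 for Hsp70Bb, -2.09 for Hsp70Bc, -1.62 for CG3348, -1.60 for lectin-28C, -1.50 for CG10039, -1.44 for CG7025 and -1.38 for Burs. The fitted values of CG10183 (4.75, and 0.81 to 5.31 over the alternatives), Osi23 (3.34), CG11470 (2.38), CG7606 (2.37) and Gr89a (-2.09) rest in part on groups not well above background and are not measured folds. Among the lists, the median difference was -0.027 for heat shock proteins and chaperones, 0.28 for genes reported to respond to cold, -0.17 for testis markers, -0.42 for Y-linked genes and -0.035 for proteasome genes. Probes assigned to no gene, which no comparison used, were called less often after cold than genes. Of 8018 such probes, 227 were higher and 130 lower in reinverted males (4.45% called), and 48 higher and 47 lower in Oregon R (1.18%). Of 12386 genes, 1988 and 3854 were called in these 2 comparisons. The probes without a gene were fitted and adjusted by themselves and were not matched to genes for signal level. The rates thus rest on unlike cutoffs and do not show that such probes respond less to cold. Between strains 40.6% of them were called at room temperature and 40.3% after cold. The direct test of the difference between strains called 3 of the probes without a gene.

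Yolk and eggshell genes stood 3.28 (median of 15) above the room-temperature mean on Oregon R cold-shock replicate 1. A second list of ovary and eggshell genes was higher on that array than on replicate 2 by a median of 1.54, in 18 of 19 genes, which is consistent with female tissue in that sample. Defects of single spots are argued against by other probes of the same genes (median excess 1.57, n = 2). The excess was not shared by cold-shock replicate 2, a single array, where the list lay 0.11 above room temperature. In reinverted males 14 of the same 15 genes had a positive change after cold (median 0.39, none called). Their medians were 0.21 and 0.50 above room temperature on the 2 cold-shock arrays of that strain, so a smaller effect of cold stays open. Signals on the array were 2.20 for Yp1 and 1.95 for Yp2; Yp1 was also at 0.87 on Oregon R room-temperature replicate 2, where Cp36 lay at -6.67. Other explanations were not tested.

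Of the testis and Y-linked lists, 11 of 34 and 7 of 9 genes were higher after cold in Oregon R males, and the lists had adjusted p = 0.88 and 0.93 with an estimated correlation. A single array is argued against for the testis list, since its lowest median with 1 of the 4 arrays left out was 0.16, against 0.18 with all. A second list, of primary spermatocyte genes, had a median change of 0.23 with 11 of 14 positive, which is consistent with a larger share of testis RNA on the cold-shock arrays. However, 2 of the 14 passed by themselves, and the lower quartile of 0.027 shows that part of this list moved little, which such a share alone would leave unexplained. Whether the males differed in testis size or the genes in regulation stays open, as does the array position, which cannot be told apart from the temperature.

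At the brightest tim probe signal fell after cold in both strains while per rose. Collection at another time of day stays open: the change of per minus that of the brightest tim probe was at least 1.93 in both strains, which only restates the pattern, and the second tim probe rose with per. A switch between tim transcripts stays open as well. The second tim probe moved against the brightest probe by 6.19 in Oregon R and 7.37 in reinverted males. This shows that the 2 probes responded unequally but not why, and it had been seen before the test was chosen. Which transcripts the probes capture was not tested, and the cold and the array position cannot be told apart.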

How the results depend on the processing

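Alternatives that left out saturated probes, replaced the local background of defective spots under normexp, or crossed the pairs were added after seeing the data. Slide as a block was not run, since each strain lies on 1 slide. The X chromosome measure stayed on the same side of the threshold under every alternative run.

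Normexp gave 180, 230, 1024, 2, 2471 and 2570 genes for the cold effect in reinverted males, in Oregon R, on average, for their difference, and between strains at room temperature and after cold. Under it the median of all genes was -0.11 in Oregon R, against -0.012, and it called 13 lists there and 9 for the difference, and gave overlaps of 45 higher and 37 lower with r = 0.24. On Oregon R room-temperature replicate 2, 2 spots with local background above their signal set its lowest values to 653 against 57.4 to 59.0 elsewhere. With these spots given the array's median background the value was 58.2 and the counts were 1942, 3800, 3054, 212, 5750 and 6114. It reversed, in Oregon R, Y-linked genes (-0.20), CG32551 (-1.06), CG14089 (-1.26), lncRNA:CR30121 (-0.96), SNCF (-1.26), Ppr-Y (-0.081) and kl-5 (-0.22); on average, cuticle proteins (-0.41), CG14089 (-0.38) and Desat2 (-0.23); and for the difference, Y-linked genes (0.10), Gr89a (0.45) and CG10039 (0.37).

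The mean of all probes reversed tim (2.21 in reinverted males, 1.84 in Oregon R, 2.02 on average, 0.0095 between strains after cold) and Trl in reinverted males (2.8e-04), and called 6 lists in Oregon R and 7 between strains at room temperature. The trend gave 318 differing genes and the replicate block 72; crossed pairing gave 1744 in reinverted males. A fit of the Oregon R arrays alone gave 2147 genes, and no strain term 775 on average. The overlap r was 0.50 without a filter and 0.58 with signal on all 8 arrays. Quantile normalization called 5 lists on average, median centring 8 for the difference, and fry 5 in Oregon R, 2 on average, 2 for the difference, and 16 and 12 between strains. With an estimated correlation 0 lists were called in each of the 6 comparisons. For these the cause was not tested.

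Leaving out 1 array gave 817 to 2162 genes in reinverted males, 1144 to 3593 in Oregon R, 2122 to 2877 on average, 31 to 278 for the difference, and 4113 to 5931 and 4285 to 5930 between strains; a lone array was assumed to vary like the other groups. Lists called ranged from 4 to 7, 2 to 6, 2 to 9, 3 to 13, 4 to 8 and 3 to 5 in the same order. Overlaps ranged from 248 to 384 higher and 263 to 749 lower, with r from 0.47 to 0.56. Between 78.0% and 83.8% of probes per array were well above background, with the lower shares on the reinverted arrays. This limits folds to bounds for genes without signal in a group.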

Other observations

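The tests of probes within a gene and of call rates on the X chromosome, and the list of post-meiotic spermatid genes, were chosen only after the results they follow were seen.

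Beyond the brightest probe, 5870 pairs of probes in 4241 genes were compared for unequal response to cold. Pairs differed at 155 in reinverted males and 23 in Oregon R, and 20 differed in the same direction in both strains, against 0.324 expected of independent lists. The gene tim had the largest of these. The expected count does not allow for the fitted spread of a pair, which both strains shared. UGP, which encodes the enzyme that makes UDP-glucose, rose by 2.78 at a second probe (3L, 9343967 to 9344026) in reinverted males and by 2.60 in Oregon R, with 0.19 and -0.14 at its brightest probe. At a second probe CG10077 had -1.65 and -1.57, and at a further probe -1.40 and -1.40, against -0.05 and 0.05 at its brightest probe. The gene gol had 0.59 and 0.35, and 0.13 and 0.16 at a further probe, against -1.31 and -1.01 at its brightest. Roc1a had 1.72 and 1.05 against -0.12 and -0.19, and SerRS-m 1.06 and 0.78 against -0.03 and -0.30. The 2 SerRS-m probes overlap (3R, 11167811 to 11167870 and 11167868 to 11167927) and are assigned to the same transcript. These genes were chosen after their values were seen.

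Genes were called unequally often by chromosome arm. After cold 13.1% of X-linked genes passed in reinverted males, against 16.7% of autosomal genes, and 24.2% against 32.5% in Oregon R. Against all other arms, the 79 genes of chromosome 4 were also called less often in both strains (5.06%, adjusted p = 0.015, and 10.1%, adjusted p = 8.3e-05). By the same Fisher test genes of 3R were called more often in both (adjusted p = 0.0079 and 0.023). Those of 2L were called more often in Oregon R (34.1%, adjusted p = 0.0044). The other arms in this test include the X chromosome, whose low rate alone makes the remaining arms look high. Against the 16.7% and 32.5% of all autosomal genes, 3R had 17.9% and 33.1%. A low rate was thus seen on chromosome 4 as well as on the X chromosome, by a test that takes genes as independent. Of the 125 genes whose cold effect differed between strains, 5 were X-linked. Autosomal genes drawn to match the levels of the X-linked ones gave 340.8, 646.7 and 24.4 calls on average for these 3 comparisons, and 0 of 10000 draws had as few as the 258, 476 and 5 observed. The draws treat genes as independent, although genes can vary together across arrays. Between strains X-linked genes were also called less often, 41.3% against 46.7% of autosomal genes at room temperature and 41.7% against 50.65% after cold. The low rate is thus not particular to the cold response.

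Of the other fixed lists, 2 of 42 gut digestive enzymes rose and 5 fell in Oregon R, and 6 rose and 2 fell in reinverted males. Of 78 cytochrome P450 genes 11 rose and 7 fell in reinverted males, and 6 rose and 11 fell in Oregon R. Photoreceptor and eye pigment genes had 2 higher and 3 lower of 26 in reinverted males, and 1 higher and 4 lower in Oregon R. None of these lists, nor those for glycolysis, the unfolded protein response, oxidative stress, fat body, muscle and neurons, passed camera in any of the 6 comparisons, although fry called some of them between strains. The signs of median, mean and test differed in 28 of 162 list tests, 0 of which were called. Post-meiotic spermatid genes had a median change of 0.30 in Oregon R, with 13 of 13 positive.

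The 3024 genes of the average cold effect were set against every split of the 8 arrays into 4 and 4. Of 35 splits 2 gave as many genes, the real split and the split by strain, with 4929 genes, which points to the difference between strains or slides. The split by strain could not be fitted with strain as a term, so its count and the 3024 come from unlike models, and this count leaves open whether chance is excluded. Among the 34 splits fitted with that term, the highest besides the real split gave 1 gene. Without the term in any split, the real split gave 775 genes, the split by strain 4929 and each other split 0. Every split besides the real one leaves part or all of the cold effect in the residual spread. Without the term, every split besides that by strain also leaves the strain difference there. Both lower the counts of the other splits, so these counts cannot decide whether chance is excluded.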
